A study of Mus musculus with 8 samples.

How the data were processed

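RNA of EpCAM-positive cells, sorted by FACS from dissociated pancreatic tumours of 8 mice, was measured by RNA sequencing, with 1 library per tumour. Per the labels, the tumours were taken at 44 to 49 days of age, RNA was extracted with a NucleoSpin RNA II kit, and libraries followed standard Illumina protocols, with neither the kit nor its strandedness stated. Groups were taken from the sample titles, with 4 tumours labelled KO and 4 labelled WT, and the genotype labels divided the latter into 2 f/+ and 2 +/+ tumours. Replicate numbers follow the order in which samples were listed and pair no tumours. The submitters' processing notes name FastQC 0.11.2, STAR 2.4.0k, HOMER (version not given), edgeR 3.6.8 and the mm10 build, without saying what each was used for.

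The authors deposited a table of raw gene counts and a table of FPKM values. Per the file headers, the counts are whole-number tags in exons of mm10 RefSeq transcripts, counted by HOMER's analyzeRepeats.pl on the plus-strand setting, with 1 transcript kept per gene and no normalization. Per the file headers, the deposited FPKM values came from the same program, per kilobase of the kept transcript and with a normalization setting of 1000000. For transcripts shared by both tables, the FPKM values imply library totals of 26.4 to 40.8 in units of 1000000 reads, which no header gives. The kept transcript was the same in both tables for 20736 of 24537 genes and differed for 3801, Lifr among them. Reads counted on 1 strand separate antisense partners only if the libraries were stranded, and near-identical gene copies can share reads, so the values of such copies are uncertain.

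The counts summed to between 14938875 and 22698340 per tumour, which was 73.5% to 80.2% of the totals in the headers. Of the 24537 genes, 4952 had no count in any tumour. Log2 CPM correlated at 0.955 to 0.980 between tumours of the same group and at 0.921 to 0.971 between groups, and no 2 libraries agreed within sampling noise (smallest chi-square per degree of freedom 32.4). In each group 3 tumours had high Xist and 1 had Y-chromosome transcripts. No column of other samples was in the tables.

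Genes were tested in R 4.3.3 with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust off) after TMM scaling and filterByExpr (minimum count 10, minimum total count 15), which left 14728 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold limit. TMM factors were 0.890 to 0.965 in the tumours labelled KO and 1.05 to 1.10 in those labelled WT (exact permutation p = 0.0286), and the common biological coefficient of variation was 0.247. CPM values are TMM-scaled, log2 fold changes are labelled KO minus labelled WT with their standard errors, and levels are mean ± SD. The 3 Lifr genotypes were also fitted together (15284 genes), which shares 1 estimate of the spread. The comparisons of the tumours labelled KO with f/+ and with +/+ tumours share the libraries labelled KO, so they are not independent.

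Before the data were examined, 48 gene lists were fixed, covering signalling, differentiation, tumour subtypes, metabolism, other cell types, RNA quality and sex. Some lists share genes and are not independent. In another list as well were 3 of 25 epithelial, 4 of 17 ductal, 5 of 21 tumour-initiating, 3 of 15 WNT and 3 of 18 RAS-MAPK genes. The 42 lists with at least 5 tested genes were tested with limma 3.58.1 (camera on voom values, preset inter-gene correlation 0.01, two-sided), with camera at an estimated correlation and fry beside it. For lists of other cell types, quality and sex, the mean log2 CPM per tumour was compared by an exact two-sided permutation test over the 70 assignments of the tumours, which cannot give a p below 0.0286. The counts adjusted over the list alone used the same edgeR p-values. Called genes within 20 Mb of Lifr were compared with those elsewhere by Fisher's exact test, with Lifr left out. The mm10 coordinates are those of the deposited tables, and the annotated extent of the Lifr gene is from GENCODE M21.

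The genes named were fixed by a rule written beforehand. It took Lifr, Lif, Il6st, Osmr and Socs3 always, then the 12 largest rises and 12 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the groups (2728 genes met this, with predicted genes and pseudogenes passed over). It also took from each list described up to 4 called members with the smallest p, or up to 2 where none was called, and the called genes with the smallest p between f/+ and +/+ tumours. A few genes that met the rule are not reported here and are left out of counts of named genes, while the lists were tested with all their members. Epcam was named by its list and as the antigen of the sort, and Trp53 was used in a test described with the closing observations.

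The tests were run first on simulated counts. Of 14728 genes drawn at the real means, dispersions and library sizes, 200 were changed, and the edgeR test called 50 of 100 changed by 1 log2 unit and 93 of 100 changed by 2 with the right sign, along with 11 unchanged genes. Camera called the 1 list that was shifted and 1 of the others among 42 lists. The simulated genes were drawn independently of each other. In the data the estimated correlation within a list reached 0.86 (acinar list), so this run does not measure false list calls at the preset correlation. Alternatives were other scalings (DESeq2 size factors, library totals, abundant genes left out), other filters for low counts (none, or a CPM of at least 1 in at least 4 tumours), other tools (DESeq2 1.42.0, edgeR's likelihood ratio test, limma voom and limma trend on log2 of FPKM plus 1 or 0.1), either control genotype alone, a linear allele term, a sex covariate and leaving out each tumour. Added after seeing the data were an acinar covariate, leaving out the most acinar tumour of each group, and scaling to the epithelial list. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.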

Results

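RNA was sequenced from EpCAM-positive cells of 8 pancreatic tumours, each from a separate mouse on the FVB/NJ background. The mice carried Cre recombinase under the Pdx1 promoter, which is active in pancreatic epithelium, with floxed Trp53 and a luciferase reporter among its targets. In the 4 tumours labelled KO both alleles of Lifr, the receptor subunit for leukaemia inhibitory factor (LIF), were floxed (f/f). The 4 tumours labelled WT were not uniform in genotype: replicates 1 and 2 carried 1 floxed allele (f/+) and replicates 3 and 4 carried none (+/+). The mice were 44 to 49 days old. The question was how gene expression differed in sorted tumour cells with Lifr deficiency. Gene counts summed to between 14938875 and 22698340 per tumour, with no difference between the groups detected (exact permutation p = 0.971). Between 17360 and 18000 genes had at least 1 count in a tumour. The 50 most abundant genes took 12.6% to 19.9% of the counts, a share 3.61 percentage points higher in the tumours labelled KO (exact permutation p = 0.0286, the smallest that 4 against 4 allows).

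Lifr itself was higher, not lower, in the tumours labelled KO. The transcript in the count table (NM_013584, mm10 chromosome 15, 7140542 to 7197489, plus strand, inside the annotated gene from 7090614 to 7197489) was at 158, 205, 150 and 220 CPM (counts scaled to a library of 1000000) in replicates 1 to 4 labelled KO. It was at 126 and 93.7 CPM in the 2 f/+ tumours and at 71.8 and 99.6 CPM in the 2 +/+ tumours. The means were 183 ± 34.5 CPM and 97.8 ± 22.2 CPM (SD, n = 4 each), a log2 fold change of 0.90 ± 0.19 (SE), with a 95% interval of 0.48 to 1.33 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0121). All 4 tumours labelled KO lay above all 4 labelled WT. The log2 fold change was between 0.78 and 1.05 with any 1 tumour left out. A shorter Lifr transcript in the FPKM table (NM_001113386) was at 12.7 ± 2.08 against 6.48 ± 1.40 FPKM (SD, n = 4 each, exact permutation p = 0.0286). The floxed exon is not given in the labels, and counts over a whole transcript do not test whether that part was deleted. The groups are therefore named by their labels throughout, and each direction given between them rests on those labels. Against the 2 f/+ tumours alone the Lifr difference was 0.74 and was not called (edgeR adjusted p = 0.0638).

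**Figure D1:**
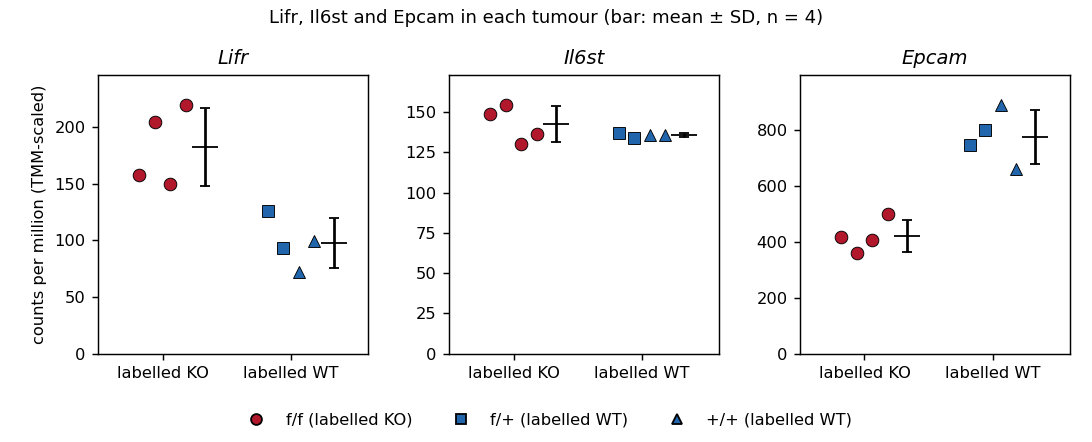
CPM (TMM-scaled counts, linear axes from 0) of Lifr, Il6st and Epcam in each tumour, with circles for f/f tumours labelled KO, squares for f/+ and triangles for +/+ tumours labelled WT, and bars for the mean ± SD of 4 tumours. Lifr lay between 150 and 220 in the tumours labelled KO and between 71.8 and 126 in those labelled WT, while Epcam averaged 421 and 775.

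Other members of the receptor pathway moved in both directions. Of 16 ligands and receptors of the LIF and interleukin-6 family, 4 rose, 3 fell and 9 did not pass, the same counts as when adjusted over the list alone. Il27ra, a subunit of the interleukin-27 receptor, rose by a log2 fold change of 1.85 ± 0.39, and Il6ra, the interleukin-6 receptor, by 0.67 ± 0.17. Clcf1, a ligand of the ciliary neurotrophic factor receptor, was lower (−0.64 ± 0.09), though 0.081 higher with libraries scaled to the epithelial list, which by construction moves every gene up. Lif was at 85.3 ± 38.7 against 61.9 ± 16.3 CPM, and Il6st, which codes for the shared subunit gp130, at 143 ± 11.2 against 136 ± 1.25 CPM (a log2 difference of 0.072 that turned to −0.11 with library totals alone). Osmr, the oncostatin M receptor, was at 28.6 ± 11.0 against 36.8 ± 8.89 CPM (SD, n = 4 each), and none of these 3 genes passed the test (edgeR adjusted p = 0.298, 0.501 and 0.400). The Lif difference rested on KO replicate 1 (142 CPM, other tumours labelled KO 59.3 to 76.1), and its log2 fold change went from 0.46 to 0.089 without that tumour and to 0.12 with the mean log2 CPM of the acinar list as covariate. The list was not called (camera adjusted p = 0.753). In a list of 20 genes of JAK and STAT3 signalling and response, 3 rose and 17 did not pass, with 5 higher when adjusted over the list alone. Socs3, a feedback inhibitor of the pathway, rose from 439 ± 91.3 to 656 ± 77.5 CPM (log2 fold change 0.58 ± 0.16, edgeR adjusted p = 0.0358), and Jak3 (0.51) and Hif1a (0.81) rose with it. The STAT3 list was called with a preset correlation (camera adjusted p = 0.0154, and adjusted p = 0.572 with an estimated correlation) and its call was lost without KO replicate 1 (camera adjusted p = 0.0759). The STAT3 means overlapped, with WT replicate 4 (7.39) above KO replicates 3 and 4 (7.23 and 7.19). With 1 tumour left out the edgeR call was lost for Socs3 (KO replicate 1, 2 or 4 or WT replicate 1, 2 or 3, highest adjusted p = 0.0959), Jak3 (KO replicate 1, 2 or 3 or WT replicate 1, 2 or 3, 0.0742), Hif1a (KO replicate 1 or 2 or WT replicate 2 or 3, 0.0959) and Il6ra (KO replicate 2 or WT replicate 2, 3 or 4, 0.0593). Macrophage markers were also higher in these tumours, by 1.26 in mean log2 CPM.

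Across the transcriptome, macrophage, interferon and MHC class I lists were called higher and epithelial and ductal lists lower in the tumours labelled KO by camera with a preset correlation. With an estimated correlation 0 of 42 lists were called and 6 had an unadjusted p under 0.05. Of 14728 genes tested, 3216 were called, with 1630 higher and 1586 lower in the tumours labelled KO, and 5300 had an unadjusted p under 0.05. Among the called genes, 410 rose and 418 fell by more than 2-fold. The groups did not overlap in 2909 of the called genes and in 25.5% of all tested genes, against 2.86% by chance. The largest rises that separated all tumours were Retnla (resistin-like alpha, log2 fold change 3.59 ± 0.57, from 83.2 ± 44.8 to 1002 ± 316 CPM), Fcrls (3.49), the endothelin receptor gene Ednrb (3.24), Dpt (dermatopontin, 3.005), the lectin genes Cd209g (2.98) and Cd209f (2.89), the lysozyme gene Lyz1 (2.90), the interferon-inducible Ifi27l2a (2.64) and Slfn5 (2.56), Gfi1b (2.63), Ms4a4c (2.60) and the folate receptor gene Folr2 (2.59). Cd209f and Cd209g, and Lyz1 and Lyz2, have near-identical copies whose reads the counting could have split, so their values are uncertain. Dpt is also in the fibroblast list, and the macrophage list was higher by 1.26 in mean log2 CPM in the same tumours. The cells that gave the largest rises were not told apart.

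The largest falls included secreted products of gastric and ductal epithelium. Muc6, a gastric gland mucin, fell from 444 ± 270 to 79.6 ± 52.4 CPM (log2 fold change −2.48 ± 0.55), and Mmp7, a metalloproteinase of duct epithelium, from 282 ± 92.0 to 60.8 ± 25.1 CPM (−2.21 ± 0.38, SD, n = 4 each). Pgc, which codes for pepsinogen C, was 5.28-fold lower, the neuropeptide gene Npy 5.67-fold lower and the aldo-keto reductase gene Akr1b7 6.16-fold lower. The others were Mfsd7c (−3.29), Dpcr1 (−2.48), the RNA-binding protein gene Igf2bp1 (−2.45), Bmp8b (−2.42), the ribonuclease genes Ang3 (−2.25) and Ang5 (−2.24), whose values are uncertain because these copies share reads, and Tll1 (−2.14). Some of these folds rested largely on 1 tumour labelled WT. Mfsd7c had 839 counts in WT replicate 3 against 44 to 75 in the others with that label, and Ang3 1448 against 211 to 334. Ang5 had 1438 there against 210 to 330, and Bmp8b 405 in WT replicate 2 against 44 to 109. Mfsd7c had a spread of 17.4 CPM around 11.6 CPM in the tumours labelled WT, and its edgeR call was lost when any tumour labelled KO or WT replicate 1 was left out (highest adjusted p = 0.112). So were those of Dpcr1 (any tumour labelled KO or WT replicate 2 or 3, 0.0848), Bmp8b, Ang3 and Ang5 (any tumour labelled KO, 0.0888, 0.0714 and 0.0716), Npy (KO replicate 1, 2 or 4, 0.0716), Igf2bp1 (KO replicate 2, 0.0539) and, among the rises, Cd209g (KO replicate 1 or 2 or WT replicate 1 or 2, 0.0637). The count of called genes was 1755 without KO replicate 2, 2077 without WT replicate 3, and 1892 without the tumour of each group that held most acinar RNA (KO replicate 1 and WT replicate 2, an alternative added after seeing the data). It was 1106 with only the +/+ tumours as controls, 1926 with only the f/+ tumours, and 47 with the number of unfloxed Lifr alleles as a linear term in place of the labelled group. Scaling by library totals alone moved the median log2 fold change of all genes from 0.011 to −0.17 and the share of calls that were higher from 50.7% to 22.5%. The FPKM values, which have no such scaling, gave 23.5% with a pseudocount of 1. With libraries scaled to the epithelial list, the 12 largest falls all stayed called lower, from −2.48 (Mfsd7c) to −1.30 (Tll1). They were picked as the largest, so this is no separate support.

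Epithelial identity genes took a lower share of the RNA in the tumours labelled KO. Of 25 epithelial genes tested, 18 fell, 0 rose and 7 did not pass (22 fell when adjusted over the list alone), with a median log2 fold change of −0.73. Epcam, the antigen used for the sort, fell from 775 ± 96.5 to 421 ± 57.7 CPM (SD, n = 4 each, log2 fold change −0.88 ± 0.13). The keratin gene Krt7 was lower by 2.28-fold, the splicing regulator Esrp1 by 1.91-fold and the desmosome gene Dsp by 1.66-fold. Of 17 ductal genes, 10 fell and 0 rose (11 fell adjusted over the list alone), among them Aqp1, a water channel (−1.22), and the transcription factor gene Sox9 (−0.73). Both lists were called (camera adjusted p = 9.6e-11 and 8.7e-06), and neither was with an estimated correlation (adjusted p = 0.277 for both). In the same tumours the macrophage list was higher. The epithelial list took 0.406% to 0.557% of counts in the tumours labelled KO against 0.823% to 1.17% in those labelled WT, while the macrophage list took 2.31% to 2.87% against 1.04% to 1.74%.

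**Figure D2:**
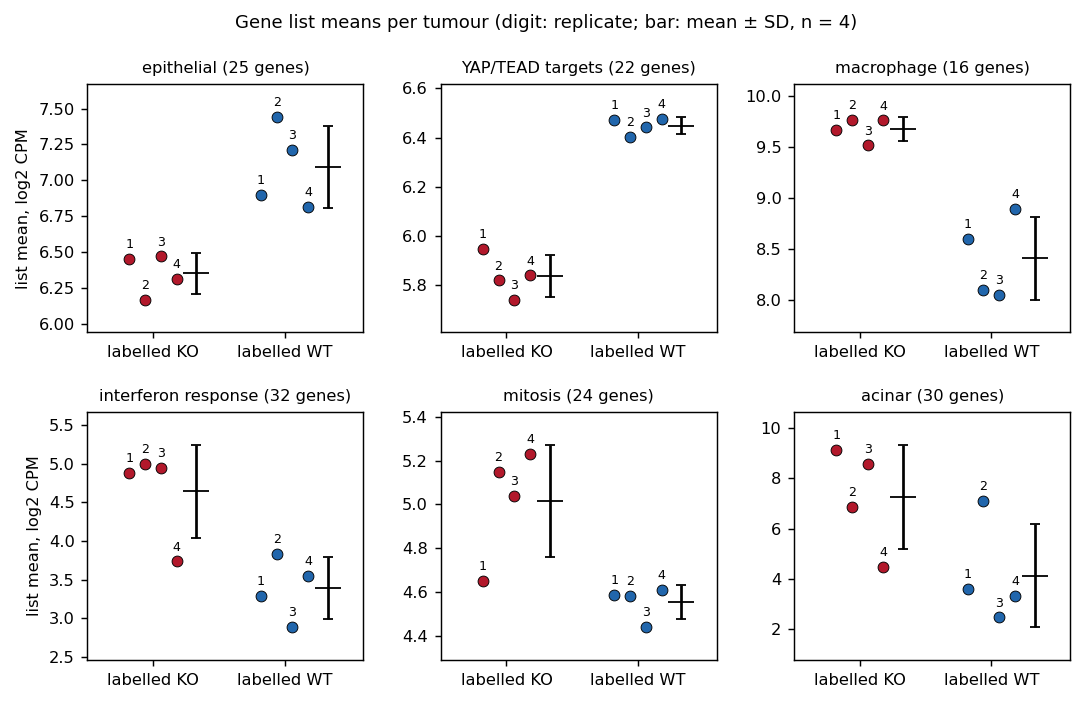
Mean log2 CPM over the genes of 6 lists in each tumour, with digits for replicate numbers and bars for the mean ± SD of 4 tumours (axes do not start at 0). With this scaling, epithelial and YAP/TEAD means were lower and macrophage means higher in all 4 tumours labelled KO (the YAP/TEAD median turned to 0.095 with libraries scaled to the epithelial list), while the interferon mean of KO replicate 4 (3.73) lay below that of WT replicate 2 (3.83) and acinar means overlapped.

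Genes of tumour differentiation and of the stem-like state fell together with the epithelial genes, and with libraries scaled to the epithelial list the medians of these 4 lists were slightly above 0 (0.012, 0.054, 0.073 and 0.15 in the order given here). Of 26 genes of the classical pancreatic tumour subtype and gastric lineage, 13 fell and 0 rose (14 fell adjusted over the list alone), including Agr2 (2.60-fold lower), Onecut2 (2.03-fold), Ctse, which codes for cathepsin E (1.99-fold), and Tspan8 (1.76-fold). The mean of KO replicate 3 (6.02) lay above that of WT replicate 1 (5.87). Of 18 markers used for tumour-initiating cells, 8 fell and 0 rose (9 adjusted over the list alone), among them Sox9, Cd24a (−0.73), Nes (−0.80) and Tspan8. Of 15 basal or squamous subtype genes only Krt4 (−1.63) and Anxa8 (−1.02) were called, both lower, also when adjusted over the list alone. Laminin and other basement membrane and adhesion genes fell in 9 of 17 cases and rose in 0 (10 fell adjusted over the list alone), with Lama5 (−1.09), Lamb3 (−1.03), Lamb1 (−0.80) and the tetraspanin gene Cd151 (−0.57) as examples. These 4 lists were called with a preset correlation (camera adjusted p = 1.8e-05, 0.000251, 0.00495 and 1.7e-05) and lost with an estimated one (adjusted p = 0.411, 0.277, 0.277 and 0.277 with an estimated correlation). The macrophage list was higher by 1.26 in mean log2 CPM in the same comparison. With libraries scaled to the epithelial list, Agr2 (−0.67) and Krt4 (−0.88) stayed called lower (edgeR adjusted p = 0.0401 and 0.0428). Cd24a and Cd151 turned above 0, and the other genes named here were below 0 and not called.

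Targets of several growth pathways were lower as well. With libraries scaled to the epithelial list, which moves every gene up, the medians of the 4 lists were 0.095, 0.021, 0.38 and 0.36 in the order given here. YAP/TEAD targets fell in 14 of 22 cases, rose in 1 and did not pass in 7 (16 fell and 1 rose adjusted over the list alone), and their list means did not overlap between the groups. Ctgf, a matrix-associated growth factor, fell from 981 ± 156 to 331 ± 143 CPM (log2 fold change −1.57 ± 0.27), and Fjx1 (−0.89), Rbms3 (−0.83) and Arhgef17 (−0.71) fell with it. WNT targets fell in 6 of 13 cases and rose in 0 (7 fell adjusted over the list alone), including Sp5 (−2.001), Ccnd1, which codes for cyclin D1 (−0.95), Rnf43 (−0.87) and Tcf7 (−0.66). Among 18 transcriptional outputs of RAS-MAPK signalling, 6 fell and 2 rose, the same counts as adjusted over the list alone, with the phosphatase gene Dusp4 (−0.79), Etv4 (−1.005) and Epha2 (−0.86) lower. Ccnd1 is in this list too, so its fall is counted in both lists. The RAS-MAPK mean of KO replicate 1 (6.25) lay above those of WT replicates 1 and 3 (6.17 and 6.19), and KO replicates 2 to 4 were at 5.88 to 5.93. TGF-beta and BMP targets fell in 3 of 12 cases (4 adjusted over the list alone), namely Smad7 (−0.53), Id1 (−0.92) and Pmepa1 (−0.82). Camera called all 4 lists (adjusted p = 4.0e-06, 0.00226, 0.0497 and 0.0245), and none was called with an estimated correlation (adjusted p = 0.0634, 0.277, 0.533 and 0.277 with an estimated correlation). The camera call of the RAS-MAPK list was lost without KO replicate 2, 3 or 4 or WT replicate 4 (adjusted p = 0.0514, 0.0860, 0.108 and 0.105) and that of the TGF-beta list without WT replicate 4 (0.0505). The edgeR calls of Tcf7, Rnf43, Id1 and Pmepa1 were lost without KO replicate 2 (adjusted p = 0.0599, 0.0585, 0.0635 and 0.0744). Those of Id1 and Pmepa1 were also lost without WT replicate 3 (edgeR adjusted p = 0.0521 and 0.0742), that of Tcf7 without KO replicate 3 (0.0505) and that of Pmepa1 without KO replicate 1 or 3 or WT replicate 1 (0.0569, 0.0720 and 0.0729). Epithelial genes were lower by a median of −0.73 and macrophage genes higher by a median of 1.20 in the same tumours. Of the genes named in this paragraph, only Ctgf (−0.82) and Sp5 (−1.36) stayed called lower with libraries scaled to the epithelial list (edgeR adjusted p = 0.0302 and 0.0261). Arhgef17, Tcf7 and Smad7 turned above 0, and the others were below 0 and not called.

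Monocyte and macrophage genes were higher in the tumours labelled KO although the cells had been sorted for EpCAM. Of 16 such genes, 14 rose, 0 fell and 2 did not pass (15 rose adjusted over the list alone). Lyz2, which codes for lysozyme and was among the most abundant transcripts, rose from 4296 ± 1360 to 11718 ± 1571 CPM. Ccr2, the receptor that recruits monocytes, rose 4.06-fold, the integrin gene Itgam 2.73-fold and Adgre1, which codes for F4/80, 2.27-fold. Of 12 genes shared by leukocytes, 9 rose and 0 fell (11 rose adjusted over the list alone), including Cd53 (0.96), Arhgdib (0.95), Laptm5 (0.90) and Cd48 (1.06). The macrophage and leukocyte lists were called (camera adjusted p = 7.3e-09 and 5.4e-06), with adjusted p = 0.277 and 0.404 with an estimated correlation. In the per-tumour comparison the mean log2 CPM of macrophage genes was higher by 1.26 and that of leukocyte genes by 0.71, without overlap between the groups (exact permutation p = 0.0286 each, adjusted p = 0.129 over 18 lists).

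Other cell types differed less uniformly. The acinar list had a median log2 fold change of 2.78, but 0 of its 30 genes were called, also when adjusted over the list alone, and its share of counts ran from 0.268% to 5.48% in the tumours labelled KO and from 0.111% to 1.599% in those labelled WT (exact permutation p = 0.0857 for the list mean). The trypsin inhibitor gene Spink1 was at 52.8 ± 35.9 against 4.54 ± 6.77 CPM (SD, n = 4 each) and Try10, whose reads may be shared with other trypsinogen copies, at 32.8 ± 28.6 against 3.83 ± 5.22 CPM. Both were called without KO replicate 4 (edgeR adjusted p = 0.0269 for Spink1 and 0.0398 for Try10) and without WT replicate 2 (0.0176 and 0.0206). The list was called with a preset correlation (camera adjusted p = 4.1e-05) and not with an estimated one (adjusted p = 0.572 with an estimated correlation). Of 20 fibroblast genes 2 rose, Dpt and Fap (1.16), also adjusted over the list alone (camera adjusted p = 0.00522, adjusted p = 0.572 with an estimated correlation), and the mean of KO replicate 4 (4.43) lay below those of WT replicates 2 and 4 (4.56 and 4.94). Of 11 B and plasma cell genes 1 rose, Cr2 (1.93), and 0 adjusted over the list alone (camera adjusted p = 0.0222, adjusted p = 0.411 with an estimated correlation). Of 6 Schwann cell genes 3 fell, Ncam1 (−1.21), S100b (−1.15) and Prx (−1.03), also adjusted over the list alone (camera adjusted p = 0.0346, adjusted p = 0.352 with an estimated correlation). Without 1 tumour the camera call was lost for the fibroblast list (WT replicate 3, adjusted p = 0.0516), the B and plasma cell list (WT replicate 4, 0.0959) and the Schwann cell list (KO replicate 2 or 3, 0.0514 and 0.0643). The edgeR calls of Fap, Cr2, S100b and Prx were each lost without KO replicate 1 (adjusted p = 0.0827, 0.0672, 0.0731 and 0.0903) and without KO replicate 2 or WT replicate 1. They were also lost without KO replicate 4 or WT replicate 3 (Fap), KO replicate 4 or WT replicate 4 (Cr2), KO replicate 3 or WT replicate 3 or 4 (S100b), and KO replicate 3 or WT replicate 3 (Prx). The Schwann cell median turned to 0.084 with libraries scaled to the epithelial list. Per tumour, B and plasma cell genes were higher by 0.95 and Schwann cell genes lower (difference −0.63), each at exact permutation p = 0.0286. The exact permutation test called 0 of the 18 lists, since the smallest adjusted p was 0.129, and 4 lists reached an unadjusted p under 0.05. These 4 lists were all at 0.0286, the smallest p that the test can give. So few lists at that p cannot pass when adjusted over 18, so the count of 0 does not argue that the cell types were alike. Per-tumour differences of the remaining cell types were 0.85 for fibroblasts, 1.04 for T and natural killer cells, 0.16 for neutrophils, 0.054 for endothelial cells, −0.37 for endocrine, −0.51 for mesothelial, −0.19 for adipocyte, 0.48 for enterocyte and −0.14 for erythroid genes, with exact permutation p between 0.114 and 0.886.

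Interferon-stimulated and MHC class I genes rose in the tumours labelled KO, as did macrophage and leukocyte genes, by 1.26 and 0.71 in mean log2 CPM. Of 32 interferon genes tested, 23 rose, 0 fell and 9 did not pass (28 rose adjusted over the list alone). The median log2 fold change was 1.32. Cxcl10, a chemokine induced by interferon, rose from 3.75 ± 0.539 to 16.4 ± 4.36 CPM (4.39-fold), the RNA sensors Dhx58 and Ifih1 by 2.95-fold and 1.62-fold, and Parp14 by 2.36-fold. Of 12 genes of MHC class I presentation, 11 rose and 0 fell, the same counts as adjusted over the list alone. B2m rose from 659 ± 124 to 1467 ± 183 CPM, and the immunoproteasome genes Psmb8 (0.76) and Psmb10 (0.77) and the class I gene H2-M3 (0.95), whose relatives may share its reads, rose too. Of 8 MHC class II genes only Cd74, the invariant chain gene, rose (0.62), with 0 adjusted over the list alone, and its edgeR call held in 1 of the 8 fits with 1 tumour left out (without WT replicate 1, highest adjusted p = 0.131). The interferon and class I lists were called and the class II list was not (camera adjusted p = 1.4e-09, 1.1e-07 and 0.0552), with adjusted p = 0.411, 0.277 and 0.572 with an estimated correlation. The interferon mean was 4.88, 4.996 and 4.95 in KO replicates 1 to 3, 3.73 in KO replicate 4 and 2.89 to 3.83 in the tumours labelled WT, while the macrophage means of KO replicates 2 and 4 were both 9.76.

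Proliferation genes were higher. Of 24 genes of G2 and mitosis, 12 rose, 0 fell and 12 did not pass (17 rose adjusted over the list alone), including Mki67 (from 153 ± 14.6 to 240 ± 34.0 CPM), Cenpa (1.81-fold), Kif11 (1.62-fold) and Bub1 (1.598-fold). Of 25 DNA replication genes, 8 rose and 0 fell, also adjusted over the list alone, with the helicase genes Mcm3 (1.54-fold), Mcm5 (1.598-fold) and Mcm6 (1.54-fold) and Uhrf1 (1.34-fold). The mitosis mean of KO replicate 1 (4.65) lay next to the highest of the tumours labelled WT (4.61), while KO replicates 2 to 4 were at 5.04 to 5.23. Both lists were called (camera adjusted p = 1.5e-06 and 2.1e-05, adjusted p = 0.467 and 0.277 with an estimated correlation). The macrophage list rose in the same tumours by a median of 1.20.

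Some genes of inflammation, of the unfolded protein response and of sterol synthesis also differed (the sterol median turned to 0.36 with libraries scaled to the epithelial list, which moves every gene up). Of 20 NF-kB and chemokine genes, 7 rose and 0 fell (8 rose adjusted over the list alone), with Nfkbia (0.93), Nfkbiz (0.89), Cxcl1 (0.94) and Birc3 (0.48) (camera adjusted p = 0.0213, adjusted p = 0.572 with an estimated correlation, and 0.0881 without KO replicate 1 at the preset one). Of 20 unfolded protein response genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone), with Dnajc3 (0.69), Edem1 (0.62) and Sdf2l1 (0.78) higher and Trib3 (−0.80) lower (camera adjusted p = 0.0254, adjusted p = 0.572 with an estimated correlation, and 0.101 without KO replicate 1 or 0.0609 without WT replicate 4 at the preset one). The unfolded protein response means were 7.56, 7.30, 7.45 and 6.93 in KO replicates 1 to 4, the last below all tumours labelled WT (7.02 to 7.13), and the acinar means were 9.11, 6.87, 8.56 and 4.48. With the mean log2 CPM of the acinar list as covariate, chosen after seeing the data, the median of the unfolded protein response genes (list UPR) went from 0.33 to 0.017 (camera adjusted p = 0.897). The NF-kB mean of KO replicate 3 (5.87) lay below those of WT replicates 1 and 4 (5.96 and 6.17), and the cholesterol mean of KO replicate 1 (5.53) above those of WT replicates 2 and 4 (5.52 and 5.51). Of 20 cholesterol synthesis genes, 9 fell and 0 rose (11 fell adjusted over the list alone), including Msmo1 (−0.57), Sqle (−0.52) and Fdps (−0.49) (camera adjusted p = 0.000157, adjusted p = 0.487 with an estimated correlation). With 1 tumour left out the edgeR call was lost for Nfkbiz (KO replicate 1, adjusted p = 0.0512), Birc3 (KO replicate 2, 0.0545), Cxcl1 (KO replicate 1 or 2 or WT replicate 3, at most 0.0558), Edem1 (KO replicate 2 or WT replicate 2, 3 or 4, at most 0.0817), Sdf2l1 (KO replicate 1, 2 or 3 or WT replicate 1, 2 or 3, at most 0.0821) and Fdps (KO replicate 2 or 3 or WT replicate 1 or 3, at most 0.0719). Immediate-early and heat-shock genes, which tissue dissociation can raise, had 0 of 20 called, also adjusted over the list alone, and a median of 0.15 (camera adjusted p = 0.139), with the messenger RNA decay factor gene Zfp36 at 2096 ± 244 against 1442 ± 289 CPM. The macrophage list was higher by 1.26 in mean log2 CPM beside each of these groups.

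**Figure D3:**
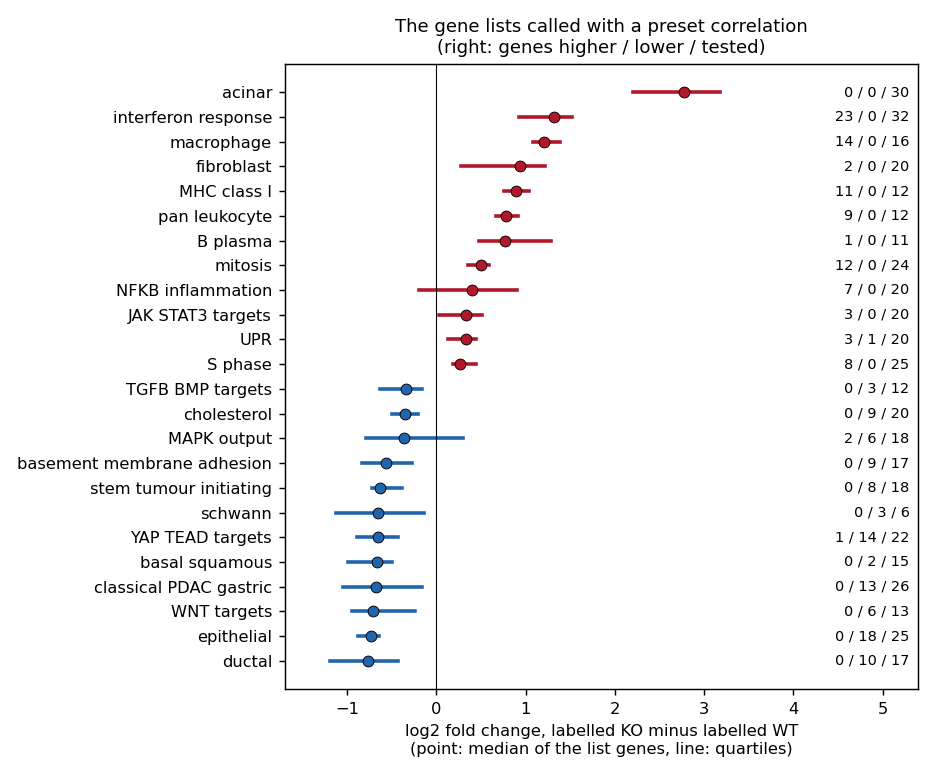
Median and quartiles of the log2 fold change (tumours labelled KO minus labelled WT) over the genes of each of the 24 lists called by camera with a preset correlation, with the numbers of genes higher, lower and tested at the right. Medians ran from −0.77 in the ductal list to 2.78 in the acinar list, of whose 30 genes 0 were called.

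In all, 24 of 42 lists were called with a preset correlation of 0.01, 12 higher and 12 lower. With an estimated correlation 0 were called and 6 had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 19. When the libraries were instead scaled to the epithelial list, an alternative added after seeing the data, the median of all genes moved to 0.74. This scaling moves every gene up by about the same amount, so small falls turn to above 0 under it by construction. Of the 132 named genes that were called, 91 were called in each of the 8 fits with 1 tumour left out, and leaving out KO replicate 2 lost most calls (40). Of the 24 called lists, 16 were called in each of those fits.

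Several lists that were not called held members that moved in opposite directions. Macrophage genes were higher by 1.26 in mean log2 CPM in the same tumours, and the cells behind these changes were not told apart. Among 21 mesenchymal and EMT genes, Zeb2 (1.24) rose, Snai2 (−1.32), Cdh2 (−0.82) and Mmp14 (−0.56) fell and 17 did not pass (1 and 3 adjusted over the list alone, camera adjusted p = 0.884). Of 16 p53 targets 5 rose and 2 fell (7 and 2 adjusted over the list alone), among them Sesn1 (1.35), Fas (1.05), Bax (0.34) and Perp (−1.08) (camera adjusted p = 0.0675, where fry gave 0.00936). Of 15 NRF2 targets 1 rose, G6pdx (0.31), and 3 fell, Gsta4 (−1.02), Me1 (−0.71) and Gclm (−0.36) (1 and 4 adjusted over the list alone, camera adjusted p = 0.303). Of 23 hypoxia and glycolysis genes, Pfkfb3 (0.69) rose and Ndrg1 (−0.71) and Ddit4 (−0.65) fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.768). Among 12 acute-phase genes Lrg1 (0.88) rose and Lcn2 (−0.97) and Hpx (−0.91) fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.268). Slc28a2 (2.06), a nucleoside transporter gene, and Dck (0.60), which codes for the kinase that activates gemcitabine, were the 2 of 14 gemcitabine-handling genes that rose, also adjusted over the list alone (camera adjusted p = 0.209). Of 8 tuft cell genes Gfi1b and Alox5ap (0.90) rose and Avil (−1.43) fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.630). Of 25 respiratory chain genes only Sdha (0.24) rose, with 0 adjusted over the list alone (camera adjusted p = 0.0595). Of 28 ribosomal protein genes 0 were called (camera adjusted p = 0.139). Single called genes in lists that were not called were Csf3r (1.13) for neutrophils, Eng (1.04) for endothelium, Msln (−2.07) for mesothelium, and Anpep (1.003) for enterocytes, also adjusted over the list alone except Eng. The endothelial list had a median of −0.017 and a mean of −0.0068 while its test pointed upward (camera adjusted p = 0.895). Of the calls in this paragraph, those of Snai2, Cdh2, Mmp14, Gsta4, Me1, Gclm, G6pdx, Pfkfb3, Lcn2, Hpx, Sdha, Eng and Alox5ap were each lost without KO replicate 2 (edgeR adjusted p from 0.0504 to 0.128). All of these except Alox5ap were also lost without KO replicate 1. Further tumours whose absence ended a call were KO replicate 3 (Cdh2, Mmp14, Lcn2, Hpx, Me1, Sdha), KO replicate 4 (G6pdx, Pfkfb3, Me1, Sdha, Eng), WT replicate 1 (Snai2, Cdh2, Mmp14, Lcn2, Hpx, G6pdx, Pfkfb3, Sdha, Eng), WT replicate 2 (Mmp14, Lcn2, Hpx, G6pdx, Pfkfb3, Eng), WT replicate 3 (Snai2, Cdh2, Gsta4, Gclm, G6pdx, Me1, Pfkfb3, Sdha, Eng) and WT replicate 4 (Mmp14, Lcn2, Me1, Pfkfb3, Sdha). The T and natural killer cell, endocrine, neutrophil, mesothelial and enterocyte lists were also not called (camera adjusted p = 0.0598, 0.316, 0.753, 0.249 and 0.343). In the first of these, 0 of 14 genes were called, Gzmb being at 7.47 ± 9.85 against 0.781 ± 1.25 CPM, and in the endocrine list 0 of 19, Pyy being at 12.1 ± 6.05 against 35.8 ± 20.03 CPM and Ins2, in the other direction, at 35.5 ± 20.6 against 16.7 ± 2.98 CPM (edgeR adjusted p = 0.0855). Pyy was called without WT replicate 2 (edgeR adjusted p = 0.0179), and Ins2 without KO replicate 4 (edgeR adjusted p = 0.0229) and by DESeq2 (adjusted p = 0.0246). Lists with fewer than 5 tested genes had no list test. They were the adipocyte list, with Lipe (0.48) higher among 3 genes, also adjusted over the list alone (not called without KO replicate 1, 2 or 4 or WT replicate 2 or 3, highest edgeR adjusted p = 0.0981), the erythroid list, where 0 of 2 haemoglobin genes with shared reads were called, and the histone and Xist lists, where Hist1h1c (0.013) and Xist (0.25) were not called. No gene of the mitochondrial or Y-chromosome lists was among the genes tested.

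The control group was then split by genotype. The f/+ and +/+ tumours differed in 1 of 15284 genes in a fit of all 3 genotypes, with 782 genes at an unadjusted p under 0.05 (edgeR) and 54 genes called by DESeq2. That gene, BC018473 (chromosome 11, 116752167 to 116757883), had 1373 and 1721 counts in the 2 f/+ tumours, 0 in both +/+ tumours and at most 1 in the tumours labelled KO, so it was at least 487-fold higher in f/+ than in +/+ tumours against a floor of 3 counts per library (75.8 ± 6.10 CPM, SD, n = 2). The 782 genes are near the number that an unadjusted threshold of 0.05 passes by chance among 15284. With 2 tumours of each control genotype, differences can have been missed. Lifr was higher by 0.36 ± 0.25 in f/+ than in +/+ tumours and was not called (edgeR adjusted p = 0.999). The tumours labelled KO differed from the +/+ tumours in 1038 genes, 479 higher and 559 lower, and from the f/+ tumours in 2036 genes, 1028 higher and 1008 lower. Lifr was higher by 1.10 ± 0.23 against +/+ tumours and by 0.74 ± 0.22 against f/+ tumours (edgeR adjusted p = 0.0383 and 0.0655). These counts rested on few tumours. The f/+ against +/+ count was 0 without KO replicate 3 (686 genes at an unadjusted p under 0.05) and 15 without KO replicate 2. Against +/+ tumours they fell to 16, 21 and 1 without KO replicates 1, 2 and 3 and to 1 without WT replicate 3. Genes at an unadjusted p under 0.05 were 4119 with all tumours and 3623, 3333, 3722 and 1930 in these 4 fits. Against f/+ tumours they were 1014, 732 and 1213 without KO replicates 1, 2 and 3, 1258 without WT replicate 1 and 1 without WT replicate 2. Here 4633 genes with all tumours and 4074, 3746, 4219, 3951 and 3301 in these 5 fits had an unadjusted p under 0.05. Where a control genotype was left with 1 tumour, that tumour was assumed to vary like the other groups.

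Called genes were not detectably concentrated around Lifr. Of 54 tested genes within 20 Mb of it on chromosome 15, Lifr left out, 14 were called (25.9%), against 21.8% elsewhere (odds ratio 1.25, 95% interval 0.630 to 2.36, two-sided Fisher's exact test p = 0.508). The odds ratio turned below 1 without KO replicate 1 (0.800) and in a window of 50 Mb (0.878).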

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

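Chosen only after the result was seen were the tests of macrophage against endothelial genes, of macrophages in KO replicate 4, of KO replicate 4 against tumours labelled WT left out likewise, and of Lifr under other scalings. Among 354 groups of 4 tumours (list means and named genes, in log2 CPM), 12 held 1 tumour whose gap to the nearest other, as a share of the range, exceeded Dixon's 95% critical value, where chance gives about 17.7. The list means concerned were those of leukocyte genes in WT replicate 2 (7.22, others 7.82 to 7.83), RAS-MAPK outputs in KO replicate 1 (6.25, others 5.88 to 5.93), interferon genes in KO replicate 4 (3.73, others 4.88 to 4.996) and MHC class II genes in KO replicate 4 (9.06, others 8.69 to 8.72). The genes were Retnla (4.10, others 6.59 to 6.85), Ccr2 (6.56, others 7.50 to 7.66) and Kif11 (4.38, others 4.54 to 4.56) in WT replicate 3, and Jak3 in KO replicate 4 (6.65, others 7.03 to 7.09). Also apart were Cxcl10 (3.34, others 4.15 to 4.30) and Cd74 (12.64, others 12.19 to 12.26) in KO replicate 2 and Sp5 (−0.32, others −1.06 to −0.94) and Msmo1 (6.28, others 5.96 to 6.004) in KO replicate 1.

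The number of genes called between the labelled groups was set against other groupings of the 8 tumours. Of the 35 splits into 4 and 4, only the real one (1 split) gave as many as 3216 called genes, and the highest other gave 26. Every other split mixes tumours of both labels, so any difference between the labels widens the spread within its groups and lowers its count. With 1 real split among 35, this comparison cannot exclude chance.

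Epithelial genes were lower and macrophage genes higher in the tumours labelled KO. A lower epithelial share that raised every other cell type alike was argued against by macrophage genes minus endothelial genes, which differed between the groups by 1.21 (exact permutation p = 0.0286). That pair was picked after the values were seen, and its result concerns only an equal rise. Fibroblast (0.85), T and natural killer cell (1.04) and B and plasma cell means (0.95) were higher, as macrophage means were. Schwann (−0.63) and mesothelial means (−0.51) were lower. A rise of some non-tumour cell types is therefore not argued against. A larger share of non-tumour cells, for which the floxed Trp53 copies should be intact, may contribute. Trp53 was higher by 0.37 ± 0.14 (SE, 95% interval 0.06 to 0.68), the outcome written beforehand for that case. It missed the threshold over all genes (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0832) and in its own exact permutation test (p = 0.0571). The groups overlapped, with KO replicate 4 at 34.9 CPM and WT replicate 4 at 39.2 CPM. As for Lifr, counts over a whole transcript do not test whether the floxed part was deleted, so Trp53 cannot decide this. The macrophage list, which shares 0 genes with other lists, held up to 2.87% of counts (Lyz2 at 11718 CPM) despite the EpCAM gate. An altered state of the tumour cells through Lifr genotype stays open and was not tested apart from cell composition.

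In KO replicate 4 interferon genes were near the level of tumours labelled WT, and it was also the lowest of the tumours labelled KO in the mean of T and natural killer cell (0.57, others 1.38 to 2.09), acinar (4.48, others 6.87 to 9.11), mesothelial (2.96, others 3.92 to 4.15), fibroblast (4.43, others 5.05 to 6.01), endocrine (1.46, others 1.98 to 2.67), neutrophil (2.91, others 3.13 to 3.81) and B and plasma cell genes (2.66, others 2.69 to 3.24), though the highest for Schwann cell genes (2.61, others 2.17 to 2.34) and between the others for endothelial (2.02, others 1.96 to 2.404), enterocyte (3.83, others 3.10 to 5.54), adipocyte (2.60, others 2.32 to 3.58), erythroid (−1.37, others −1.72 to −0.34) and leukocyte genes (8.37, others 8.27 to 8.57). Fewer macrophages were argued against, since its macrophage mean lay 0.24 above the lowest other tumour labelled KO. For a wrong label, the bound set before the result asked for over 80% of the genes called without this tumour (2937 with the interferon list left out) to lie nearer to the other tumours labelled KO, and 75.5% did, so that bound was not met and by it a wrong label cannot be told apart. Tumours labelled WT, left out likewise, had 14.7%, 16.1%, 5.83% and 31.4%, which put KO replicate 4 above the highest of them by 44.1 percentage points and argues against a wrong label, but this comparison was chosen after the first bound had been missed. Fewer cells of the types in which it was lowest stay open, no biological explanation was tested, and 1 tumour gives no spread.

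Lifr was higher in the tumours labelled KO. The scaling of the libraries was argued against, since the lowest log2 fold change over the scalings was 0.73. Lifr RNA of non-tumour cells cannot be told apart. Lifr minus macrophage genes differed by −0.35 (exact permutation p = 0.114), while Lifr minus epithelial genes differed by 1.66 (exact permutation p = 0.0286). This met the outcome written beforehand for that cause, a detected difference from epithelial but not from macrophage genes. The test as run also asked for a smaller difference from macrophage genes, which was not part of that prediction, and so gave no decision. With 4 tumours in each group, a difference that was not detected does not show that Lifr and macrophage genes moved alike. A swap of all labels or RNA that lacks the deleted part but is still counted stay open, as no exon was measured alone.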

How the results depend on the processing

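Chosen after the data were seen were the acinar covariate, leaving out the tumour of each group with most acinar RNA, and scaling to the epithelial list. Over all alternatives, comparisons kept their direction and side of the threshold in 100 cases, lost it or shrank over 1.5 times in 19, grew in 5 and reversed in 2 (an odds ratio that turned below 1, without KO replicate 1 and for 50 Mb). For lists these counts were 684, 67, 38 and 51, for named genes 3297, 604, 44 and 46, and for per-tumour cell type lists 141 and 21 (same and reversed). None of the per-tumour lists was called, so for them no call could be lost. No paired analysis was possible because the replicate numbers only follow the listing order and mark no shared animal, litter or day. Except where stated, the cause was not tested. The self-test, in which 200 of 14728 genes were changed, called 50 of 100 genes at 1 log2 unit. The data gave 3216 calls, which loosens the adjusted threshold, so that share is not the power of this comparison. Changes of that size or smaller can still have been missed at this depth and number of tumours.

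The 3216 genes called between the labelled groups were 1755 to 3241 with 1 tumour left out (1755 without KO replicate 2, 2077 without WT replicate 3), 1106 with only the 2 +/+ controls, 1926 with only the 2 f/+ controls and 1892 without the most acinar tumours, all with fewer samples. They were 47 with a linear term for unfloxed alleles, and 9735 with libraries scaled to the epithelial list. The share higher was 50.7%, against 22.5% of 4008 with library totals (median of all genes −0.17), 23.5% of 3839 and 23.5% of 3863 with FPKM plus 1 and plus 0.1 (−0.11 and −0.16), and 98.6% of 9735 with the epithelial scaling (0.74), which moves every gene up by construction. Lifr was between 0.73 and 1.62 in the 26 alternatives that compare the groups (adjusted p from 0.000138 to 0.0638 over the tools used) and lost its call with only the f/+ controls (0.74, edgeR adjusted p = 0.0638). It also lost it with the linear term (edgeR adjusted p = 0.0645), whose 0.56 is a change per unfloxed allele lost and cannot be set beside the group differences. The count of called lists was 24, and 0 with an estimated correlation (19 with fry, 20 to 29 with the others). Between f/+ and +/+ tumours the count was 0 to 15 with 1 tumour left out and 54 with DESeq2. Against +/+ tumours it was 1 to 1065 and 2630, and against f/+ tumours 1 to 1891 and 3200. The odds ratio near Lifr was 0.878 for 50 Mb and 0.800 to 1.36 with 1 tumour left out.

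Scaling the libraries to the epithelial list moves every gene up by about the same amount, so small falls turn to above 0 by construction, and that list itself is set near 0. Named genes that stayed called lower were the 12 largest falls, Ctgf (−0.82), Sp5 (−1.36), Agr2 (−0.67), Krt4 (−0.88), Msln (−1.28) and Avil (−0.72). The called lists that turned were epithelial (0.027), stem (0.054), classical (0.012), basal (0.073), Schwann (0.084), RAS-MAPK (0.38), YAP/TEAD (0.095), WNT (0.021), TGF-beta (0.36), cholesterol (0.36) and basement membrane (0.15), and of lists not called EMT (0.65), endocrine (0.25), endothelial (0.65), mesothelial (0.48), hypoxia (0.77), NRF2 (0.57) and ribosomal (0.64). The called named genes were Clcf1 (0.081), Mmp14 (0.15), Dsp (0.027), Cd24a (0.021), Arhgef17 (0.032), Tcf7 (0.075), Smad7 (0.19), Ddit4 (0.097), Ndrg1 (0.051), Msmo1 (0.15), Sqle (0.19), Fdps (0.21), Gclm (0.37), Me1 (0.054) and Cd151 (0.15), and, not called, Osmr (0.34), Rpl14 (0.52) and Rpl5 (0.33).

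Other reversals concerned results that were not called. With library totals these were Il6st (−0.11), Hist1h1c (−0.16) and the tuft (−0.064), OXPHOS (−0.079), gemcitabine (−0.12) and immediate-early (−0.034) lists, and with FPKM Il6st (−0.10 and −0.11), Hist1h1c (−0.048 and −0.046) and Xist (−0.054). With the acinar covariate they were Gzmb (−0.14) and the acute-phase (−0.18), EMT (0.15), neutrophil (−0.21), endothelial (0.094), enterocyte (−0.12) and tuft (−0.060) lists. Without the most acinar tumours they were Hbb-b1 and Hbb-bs (0.19), Hist1h1c (−0.22), Xist (−0.36), EMT (0.0082), tuft (−0.070) and hypoxia (0.077). With only +/+ controls they were Hist1h1c (−0.41), Xist (−0.17), EMT (0.15), tuft (−0.14) and hypoxia (3.46e-05), and with only f/+ controls EMT (0.18), neutrophil (−0.023) and endothelial (0.31). The linear term turned Hist1h1c (−0.15 per unfloxed allele lost) and Xist (−0.024 per unfloxed allele lost). Abundant genes left out of the scaling turned Hist1h1c (−0.015), voom Hbb-b1 and Hbb-bs (0.098) and Xist (−0.21), and voom with quality weights Hbb-b1 and Hbb-bs (0.49) and Xist (−1.49). With 1 tumour left out, ranges that crossed 0 were Hist1h1c (−0.19 to 0.40), Xist (−0.16 to 0.67), EMT (−0.15 to 0.052), endothelial (−0.15 to 0.36), hypoxia (−0.12 to 0.066), mesothelial (−0.48 to 0.049), neutrophil (−0.026 to 0.46) and tuft (−0.14 to 0.25). Per-tumour list differences that crossed 0 were neutrophil (−0.012 to 0.29, −0.30 for the median), endothelial (−0.045 to 0.26, −0.077), ribosomal (−0.062 to 0.15, −0.17), erythroid (−0.94 to 0.62), adipocyte (−0.51 to 0.16), histone (−0.12 to 0.42) and Xist (−2.25 to 2.44).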

Other observations

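Chosen only after the result was seen were the tests of YAP/TEAD, classical and mitosis genes and that of the ratio of the Lifr transcripts. The test of genes near Lifr was planned.

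A hypothesis was that the lower YAP/TEAD targets and classical genes followed from a lower epithelial share alone. Relative to epithelial genes, YAP/TEAD targets differed by 0.13 (exact permutation p = 0.571) and classical genes by 0.047 (p = 0.8286), but the epithelial list was taken as the reference after it was seen to fall and had the lowest mean log2 fold change of the lists meant to describe tumour cells (−0.76). No list could therefore have come out lower, and these tests decide nothing. A hypothesis that a larger macrophage share alone raised mitosis genes could not be decided. Mitosis minus macrophage genes differed by −0.80 and mitosis minus epithelial genes by 1.20 (exact permutation p = 0.0286 each), which met the bound written against it, but a mixture in which both cell types hold mitosis RNA gives the same values, so that bound was wrong and the test decides nothing.

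Donor-strain DNA beside the floxed allele could raise the number of called genes near Lifr. The odds ratio within 20 Mb was 1.25 with an interval of 0.630 to 2.36, so this cannot be told apart with 54 genes.

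The ratio of reads per kilobase over the short Lifr transcript to those over the long one was 1.29 ± 0.1004 in the tumours labelled KO (1.44, 1.25, 1.22 and 1.25) and 1.08 ± 0.0739 in those labelled WT (1.05, 1.02, 1.07 and 1.19, SD, n = 4 each, exact permutation p = 0.0286). The short transcript is from the FPKM table, with reads recovered from the library totals that its values imply, and the long one from the count table. Between f/+ and +/+ tumours, edgeR with all 8 tumours called BC018473 alone, while DESeq2 called 54 genes. The gene with the next smallest edgeR p, Tmem181b-ps on chromosome 17, named after its values were seen, was not called and had 159 and 180 counts in the f/+ tumours and at most 1 elsewhere (edgeR adjusted p = 0.111). Eif3j1 and Ndufs5, named likewise and not called (edgeR adjusted p = 0.169 each), were low only in the +/+ tumours. Eif3j1 had 11 and 3 counts there, 97 and 126 in f/+ tumours and 80 to 199 in those labelled KO. Ndufs5 had 1 and 1, 22 and 31, and 19 to 35. Eif3j2, which overlaps Eif3j1, had the same counts as Eif3j1 in every tumour, so they share reads and their values are uncertain. The cause was not tested.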
